A study of Mus musculus with 24 samples.

How the data were processed

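MicroRNAs (miRNAs, short RNAs that lower the output of the messages they pair with) were measured in total RNA from whole lungs of C57BL/6 mice on 24 Agilent arrays, 1 array per biological replicate. Per the labels, the RNA was extracted with a miRNeasy mini kit and 100 ng was labelled with Cy3 for a 1-colour array. The study's title speaks of fetal lungs, whereas its design text and every sample label give ages after birth, and the ages of the labels were used: day 1, day 4, day 7 and day 14 with 5 arrays each and 6 weeks, written here as day 42, with 4 arrays. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1, the version that the submitters' processing notes also name.

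Each deposited array file holds intensity values per spot and per miRNA, with no adjustment between arrays. The processed spot signal in these files was background-subtracted per spot by the authors' extraction software and falls below 0 on dim spots. The deposited table for the whole series holds log2 values for 672 names: every column has the same median of 2.41, and against the log2 total signal per miRNA of its own array each column follows a line with a slope between 0.890 and 1.08 and a Pearson correlation of at least 0.998. These values were therefore treated as log2 total signals made equal in distribution between arrays by the authors, and they served as an alternative, not as the main values. How the authors made that table after extraction is not stated in the labels.

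The array design carries 13715 spots, of which 13000 belong to 1857 probes for 650 miRNA names: 611 of mouse and 39 of mouse herpesviruses, which have no known place in a healthy lung and serve as a check of unspecific signal. A miRNA has 1 to 4 probes and a probe 5 to 20 spots. For each array, the processed signals of a probe's spots were averaged, with the 319 to 523 spots marked as outliers on that array left out, and the probes of a miRNA were summed. No miRNA spot was saturated. Each array was divided by the 75th percentile of the 228 miRNAs detected on all arrays and multiplied by 1 common factor. Values under a floor of 7.24, the median over arrays of the lowest scaled signal of a detected miRNA, were set to that floor (2.86 on the log2 scale), and log2 was taken. Detection is the deposited flag per miRNA. Of the 383 miRNAs detected on any array, the 322 detected on every array of at least 1 age were tested.

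Differences between ages were tested with limma 3.58.1 in R 4.3.3: 1 linear model over all 24 arrays with the 5 ages as groups (19 residual degrees of freedom), empirical Bayes moderation, and Benjamini-Hochberg adjustment over the 322 miRNAs within each comparison. A miRNA was called at an adjusted p under 0.05, and the number that also changed at least 2-fold was counted. All tests were two-sided. The contrasts were fixed from the design: an F-test over the ages, day 42 and day 14 against day 1, the 4 consecutive steps, and the mean of days 4, 7 and 14 against the mean of days 1 and 42, counted only where the mean of the middle ages lay above both end ages (a peak) or below both (a dip). Errors after ± are standard errors of the model unless SD is named. Where a miRNA was detected on none of the arrays of the lower age, its fold is a bound, taken with each array of the lower age at the highest of 3 values (the floor, its own scaled signal, and the lowest scaled signal of a detected miRNA on that array), and is written as at least N-fold. Values at the floor have no order among themselves. Reading and drawing used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

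Before the data were examined, 19 lists of miRNAs were fixed: the let-7, miR-29, miR-30 and miR-15/16/195 families; the miR-17, Dlk1-Dio3, miR-322 and Sfmbt2 clusters (the miR-322 cluster on the X chromosome also holds miR-503, miR-351, miR-450 and miR-542) and the embryonic stem cell clusters; miRNAs hosted by H19, Igf2 and Mest; markers of epithelium, multiciliated cells, mesenchyme and smooth muscle, endothelium, leukocytes, red blood cells, striated muscle and other organs; and the virus names. The 17 lists with at least 3 tested members were tested with limma's camera, which asks whether a list changed more than the other miRNAs, with a correlation between members estimated from the residuals; a preset correlation of 0.01 was an alternative. The lists follow textbook knowledge and were not chosen on these samples. Members of a family with a shared mature sequence may share signal between probes, so that counts of their rises or falls may not be independent.

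The miRNAs named in the text were also picked by a rule fixed in advance: for day 42 against day 1 the 12 largest rises and the 12 largest falls, and for each other comparison and the transient contrast the 6 largest in each direction. They had to be called, to be detected on every array of the higher age and, except in the transient contrast, to show no overlap between the arrays of the 2 ages. From each list, up to 4 members with the highest level and up to 2 more with the largest change were added. The 1 called miRNA of day 7 against day 4 lies outside that rule, and it and the other list members given as values were chosen after their values were seen. Names are given as on the array without the mmu- prefix; a star marks the arm of the hairpin that is usually less abundant. Positions in the genome are not given, because neither the files nor the reference hold coordinates for miRNAs, and probe sequences were not available here, so that the base composition of probes could not be tested.

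Alternatives changed 1 choice at a time, apart from normexp and the deposited table, which each changed several together. They were other scalings (the 75th percentile over all names, the median of the miRNAs detected on all arrays, quantile normalization, no scaling), the deposited log2 table, normexp background correction with an offset of 50, another summary per miRNA, a floor 4 times as high and another 4 times as low, other filters and detection flags, other variance models, the slide or the replicate number as a block, only the 2 ages compared, and each array left out in turn. The files hold no mean spot signal, so normexp was run on the median spot signal and the median local background, a change from the plan made when the files were read. Added after seeing the data were a fit without the 5 arrays whose 75th percentile lay under 75% of the median of their age, called dim arrays below, and a fit with array brightness as a covariate. That covariate was the log2 of the same 75th percentile by which each array was divided. The model was tested on simulated data of the same size: with 200 of 322 miRNAs changed it recovered 57.5% at 1.5-fold, 85.0% at 2-fold and 98.1% at 4-fold, 1.99% of its calls were false, and with no change it made 0.1 calls per run on average. The simulated miRNAs varied independently of each other, whereas the real ones varied together within ages. These figures therefore do not give the rate of false calls on these arrays. The number of arrays limits the precision of every value.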

Results

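The levels of miRNAs were followed in the lung of healthy C57BL/6 mice from birth to young adulthood, at day 1, day 4, day 7, day 14 and day 42 after birth. Mice are born with simple air sacs, which divide into alveoli mainly over the first weeks of life, so that these ages cover alveolar development. There were 5 arrays per age, except 4 at day 42. An array detected 304 ± 27.9 miRNAs at day 1 (SD, n = 5), 317 ± 20.2 at day 4 (SD, n = 5), 329 ± 9.09 at day 7 (SD, n = 5), 324 ± 17.0 at day 14 (SD, n = 5) and 298 ± 16.9 at day 42 (SD, n = 4). Day 42 and day 1 differed by -6.9 detected miRNAs per array, which is less than the spread between arrays (exact permutation test, two-sided p = 0.667). Arrays differed in brightness. The 75th percentile of the miRNAs detected on all arrays, before scaling, averaged 1539 intensity units at day 1, 1957 at day 4, 2418 at day 7, 3239 at day 14 and 3105 at day 42. Single arrays ranged from 923 to 4954. The 24 arrays lay on 3 slides of 8, each with all 5 ages. Within an age, the correlation of log2 values between arrays ran from 0.882 to 0.998.

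Across the 5 ages, 211 of the 322 tested miRNAs changed (65.5%). Age was the main difference between the arrays: the first principal component of the log2 values, which held 62.8% of their variance, followed age. The second held 22.1%, and on it the dim arrays of day 1, day 4 and day 42 stood highest, at 4.92 to 15.68. The plot of 9 miRNAs by age gives examples of the courses described in what follows, with the miR-29 family rising late, the imprinted miRNAs lower at day 14 and lower again at day 42, and miR-551b standing highest in the first week.

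**Figure D1:**
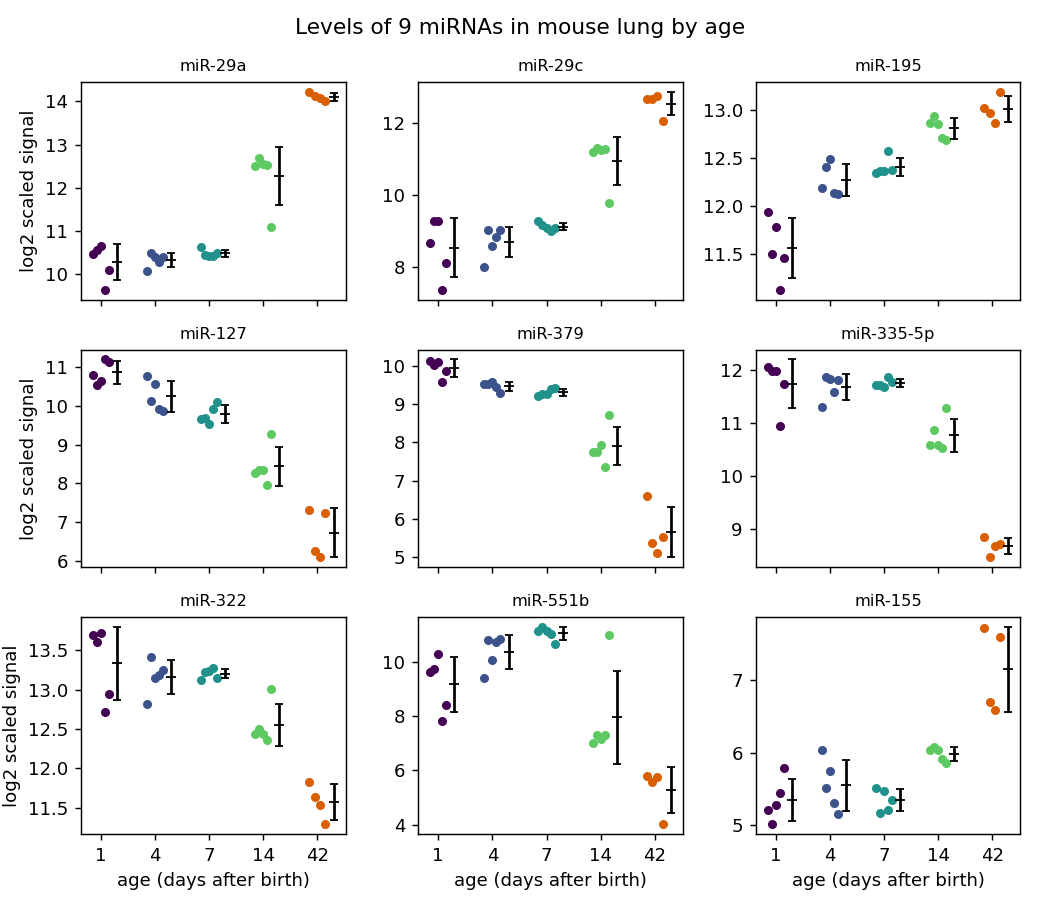
Levels of 9 miRNAs by age in days after birth. Each point is 1 array (log2 scaled signal), and the black mark with its bar is the mean with its SD (n = 5, and n = 4 at day 42). The mean of miR-29a goes from 10.28 at day 1 to 14.10 at day 42 and that of miR-127 from 10.85 to 6.73.

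Day 42 against day 1 spans the series and asks which miRNAs separate the adult from the newborn lung. The members of the miR-29 family, which hold back messages for collagens and elastin, showed the largest rises. Among them miR-29a rose by 3.82 ± 0.24 on the log2 scale, or 14.1-fold (adjusted p = 4.04e-12), miR-29c by 4.00 ± 0.34 (adjusted p = 5.12e-10) and miR-29b by 4.02 ± 0.66 (adjusted p = 1.48e-05; 1.99 and adjusted p = 0.000335 with array brightness as a covariate). The largest falls were those of the miRNAs from the imprinted Dlk1-Dio3 region, which are expressed from the maternal chromosome and are abundant in fetal tissue. In all, 41 of its 42 tested members fell, with a median of -3.56 (11.8-fold). Among them miR-127 fell by 4.12 ± 0.27 (adjusted p = 6.12e-12). Another member, miR-431, fell at least 28.6-fold to a level detected on 0 of 4 day 42 arrays. Of the 322 miRNAs, 61 rose and 138 fell.

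Among the miRNAs that met the rule for naming, the 12 largest rises also took in 2 minor arms of the miR-29 hairpins. Of these, miR-29c* rose by 2.51 ± 0.19, from a level detected on 2 of 5 day 1 arrays, and miR-29a* rose at least 2.36-fold. The others were miR-338-3p with 1.86 ± 0.25, the leukocyte miRNAs miR-155 with 1.80 ± 0.22, miR-150 with 1.60 ± 0.33 and miR-146b with 1.502 ± 0.13. They ended with miR-22* with 1.47 ± 0.17, miR-195 with 1.44 ± 0.14 and miR-100 with 1.39 ± 0.19. All of the 12 largest falls under that rule belonged to the Dlk1-Dio3 region. Besides miR-127 and miR-431 they were miR-410 (-4.67, detected on 2 of 4 day 42 arrays), miR-434-3p (-4.46), miR-379 (-4.28), miR-434-5p (-4.27, detected on 2 of 4), miR-376a (-4.26, detected on 3 of 4), miR-299* (-4.22) and miR-382 (-4.06). The last 3, miR-411*, miR-409-5p and miR-369-5p, were detected on 0 of 4 day 42 arrays and fell at least 20.2-fold, 19.2-fold and 17.3-fold. As the rule for naming asks, each of these 24 miRNAs had all arrays of 1 age above all arrays of the other.

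The Dlk1-Dio3 list had an adjusted p = 0.0706 with an estimated correlation. With its 13 members that were detected on every day 1 array and on no day 42 array put at their bounds the median stayed at -3.56. Over the 11 members detected on all arrays of both ages it was -4.01. Under every other scaling the median was negative, from -3.34 with median scaling to -2.59 with none. Within the 3 slides it was -3.47, -3.72 and -3.70. The member that did not pass the test was miR-494, at -0.47. It passed without day 42 replicate 4 (-0.68, adjusted p = 0.0374) and stood at 0.53 with no scaling. Among miRNAs of other imprinted genes, 3 of 4 tested fell. There, miR-335-5p, from the growth-linked gene Mest, fell by 3.06 on the log2 scale, and miR-335-3p fell by 3.99, to a level not detected on every day 42 array. From H19, miR-675-3p fell at least 7.85-fold to a level detected on 0 of 4 day 42 arrays. The list median was -3.04 (adjusted p = 0.182 with an estimated correlation), or -3.02 with miR-675-3p at its bound, and -1.71 over the 2 members detected on all arrays of both ages. The miRNA from Igf2, miR-483, was at -0.37 (adjusted p = 0.239) and at 0.68 with quantile normalization, 0.64 with no scaling and 0.80 in the deposited table.

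The X-linked cluster of miR-322, whose main member belongs to the miR-16 seed group and slows the cell cycle, fell in all 10 tested members (median -1.11, adjusted p = 0.3 with an estimated correlation). In it, miR-322 fell by 1.76 on the log2 scale, miR-503 by 1.81 and miR-351 by 2.68. The call for its member miR-450a-5p (-0.81) was lost without day 42 replicates 2 or 4 or day 1 replicates 1, 2 or 3. Values there ran from -0.81 to -0.58 and the adjusted p from 0.0575 to 0.123, and the value was 0.20 with no scaling. In the growth-linked miR-17 clusters 8 of 10 tested members fell (median -0.76, adjusted p = 0.458 with an estimated correlation), though with no scaling the median was 0.24. There, miR-18a fell by 2.11 and miR-17 by 1.25. The median of the miR-29 family was 4.00 (3 of 3 rose, adjusted p = 0.182 with an estimated correlation), and it lay between 3.14 with array brightness as a covariate and 5.01 with no scaling under the alternatives run.

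In the let-7 family, which marks late development, 4 of 9 members rose (5 when adjusted over the list alone) and 1 fell (median 0.34, adjusted p = 0.386 with an estimated correlation). The rises included let-7b with 1.03, let-7c with 0.97 and let-7g with 0.60, while let-7e fell by 0.57. The call for let-7e was lost without day 1 replicate 4 (-0.42, adjusted p = 0.0784), and its value was 0.09 with the 75th percentile over all names and 0.43 with no scaling. Of the miR-30 family 2 of 5 rose, miR-30a by 0.87 and miR-30b by 0.83 (median 0.46, adjusted p = 0.286 with an estimated correlation). In the family of miR-15, miR-16 and miR-195, 2 of 5 rose and 1 fell (median 0.45, adjusted p = 0.316 with an estimated correlation). Here miR-195 rose by 1.44 and its cluster partner miR-497 by 0.99, whereas miR-15b fell by 0.59. The call for miR-15b was lost without day 1 replicate 4 (-0.42, adjusted p = 0.0663), and its value was 0.07 with the 75th percentile over all names and 0.42 with no scaling. The medians of these 3 families were positive under every scaling. For the other lists of this comparison the counts adjusted over the list alone were the same as those over all miRNAs.

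Among cell type markers, 7 of 8 leukocyte miRNAs rose (median 1.55, adjusted p = 0.0706 with an estimated correlation), under every scaling with a positive median. They included miR-142-5p with 2.35 and miR-142-3p with 1.87, which are made in blood cells of all lineages. With brightness as a covariate these 2 were at 0.87 (adjusted p = 0.0331) and 0.03 (adjusted p = 0.953). Other members were miR-146a with 1.24, and miR-223 of neutrophils and other myeloid cells with 0.43. The call for miR-223 was lost without day 42 replicate 4 (0.33, adjusted p = 0.0818) or day 1 replicate 2 (0.33, adjusted p = 0.0866). The member miR-342-3p was at -0.54 (adjusted p = 0.0869) and fell without day 42 replicate 4 (-0.73), day 1 replicate 2 (-0.67) or day 1 replicate 3 (-0.66). None of the 3 red blood cell miRNAs was called by limma (0 at an unadjusted p under 0.05 as well). Their member miR-451 was at 0.41, miR-486 at 0.44 and miR-144 at 0.51 (median 0.44, adjusted p = 0.437 with an estimated correlation). However, miR-451 passed without day 42 replicate 4 (0.63, adjusted p = 0.0261) or day 1 replicate 2 (0.57, adjusted p = 0.0374), and miR-486 without day 42 replicate 3 (0.66, adjusted p = 0.0456). The value of miR-144 ran from -0.12 without day 1 replicate 4 to 1.48 without day 42 replicate 4, and with brightness as a covariate it was -2.60 (adjusted p = 0.00168), beside -0.08 for miR-451 and 0.90 for miR-486 (adjusted p = 0.0124). Of the endothelial miRNAs 3 of 4 rose (median 0.77, adjusted p = 0.3 with an estimated correlation). These were miR-126-3p, the main miRNA of vessel lining cells, with 0.79, miR-126-5p with 0.75 and miR-222 with 0.99, and the median was positive under every scaling. The call for miR-126-5p was lost without day 42 replicate 3 (0.58, adjusted p = 0.125), day 1 replicate 1 (0.65, adjusted p = 0.0778) or day 1 replicate 4 (0.65, adjusted p = 0.0527).

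Markers of multiciliated airway cells went both ways, with 4 of 6 higher and 2 lower (median 1.16, adjusted p = 0.307 with an estimated correlation; the median was -0.57 with normexp background correction). The arms from miR-34b and miR-34c rose, among them miR-34b-5p by 1.91 and miR-34c by 1.27, while miR-449a fell by 1.01 and miR-449c by 1.27. The falls were not called with the 75th percentile over all names, median scaling or no scaling. That of miR-449a was also lost without day 42 replicate 4 (-0.70, adjusted p = 0.0865) or day 1 replicate 3 (-0.78, adjusted p = 0.0518). That of miR-449c was lost without day 42 replicates 1, 2 or 4 or day 1 replicates 2, 3 or 5 (-1.21 to -0.93, adjusted p from 0.0623 to 0.105). Of 11 epithelial miRNAs 2 rose and 3 fell (median 0.10, adjusted p = 0.458 with an estimated correlation). The miR-200 family members miR-200b and miR-200c were at 0.10 and -0.16, and at 0.53 and 0.54, both called, with brightness as a covariate. By contrast miR-205, a miRNA of basal epithelial cells, fell by 1.68. Of 7 mesenchymal and smooth muscle miRNAs 2 rose and 3 fell (median 0.00, adjusted p = 0.991 with an estimated correlation). The sign of the median changed with the scaling, from -0.15 with quantile normalization to 1.01 with none. The falls were those of the fibroblast miRNAs miR-214 with -2.19, miR-199a-5p with -1.62 and miR-199a-3p with -0.78, the last of which was at 0.23 with no scaling. The smooth muscle miRNA miR-143 was at 0.03, and miR-10a rose by 0.88.

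Striated muscle is a tissue that a lung dissection could include, and 1 of its 4 tested miRNAs was called. This one, miR-208b, fell by 2.25 on the log2 scale (list median 0.43, adjusted p = 0.913 with an estimated correlation; the median was -0.38 with normexp background correction). The size of this fall rested on day 1 replicate 2, where the mean of the 4 miRNAs was 12.6 against 6.01 to 8.56 on the other day 1 arrays. Without that array miR-208b was at -1.25 (adjusted p = 0.00784) and the other members rose, miR-1 by 2.13 (adjusted p = 0.0198), miR-133b by 1.60 (adjusted p = 0.0146) and miR-133a by 1.44 (adjusted p = 0.0234), against 0.86, 0.51 and 0.35 with it. Without the 5 dim arrays, which do not include that one, they were at -0.21, -0.36 and -0.495, with none called by limma (adjusted p from 0.681 to 0.874). Of markers of other organs, the 2 tested were not called by limma (0 at an unadjusted p under 0.05 as well). Of these, miR-128 was at -0.21, but it passed as a rise with the 75th percentile over all names (0.45, adjusted p = 0.0055), quantile normalization (0.57, adjusted p = 0.00105), no scaling (0.79, adjusted p = 0.0231) and in the deposited table (0.56, adjusted p = 0.00155). The other, miR-219, was at 1.08, passed without day 42 replicate 4 (1.62, adjusted p = 0.0402) and was at -0.79 with brightness as a covariate. No member of the embryonic stem cell clusters was detected widely enough to be tested. In the repeat-rich Sfmbt2 cluster 7 of 15 members fell (median -0.40, adjusted p = 0.925 with an estimated correlation), among them miR-669c by 0.72. However, the list median was 0.26 with the 75th percentile over all names, 0.66 with quantile normalization, 0.60 with no scaling and 0.74 in the deposited table. Of the virus names, which measure unspecific signal in uninfected lung, 1 of 3 was called. The called name, mghv-miR-M1-2, fell by 1.02 (-0.72 and adjusted p = 0.0538 without day 1 replicate 4). Its slope on array brightness was -1.008 per doubling, and brightness was 1.005 higher on the log2 scale at day 42 than at day 1. With brightness as a covariate it was at -0.01 (adjusted p = 0.951). A fall of about this size may thus come from dividing an unspecific signal by a larger array factor, and does not by itself show a change in the lung. The values were -0.22 for mcmv-miR-M23-1-5p and 0.31 for mcmv-miR-m88-1 (list median -0.22, adjusted p = 0.925 with an estimated correlation, and positive under each of the other scalings).

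**Figure D2:**
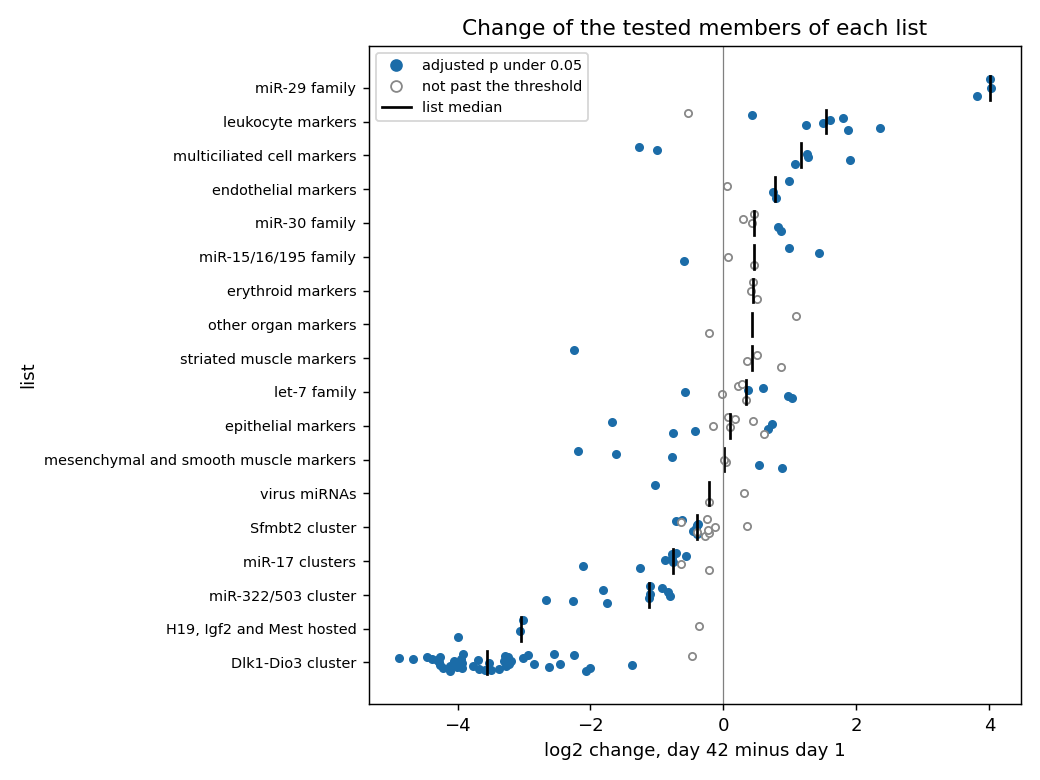
Change from day 1 to day 42 of every tested member of each list (log2, day 42 minus day 1). Filled points passed the test in limma, open points did not, and bars are list medians. All 3 miR-29 members lie near 4 and 41 of 42 Dlk1-Dio3 members lie below 0 and passed, under every scaling with the same sign of the median. The medians of the miR-17, Sfmbt2, mesenchymal and virus lists change sign with the scaling.

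In this comparison 199 of 322 miRNAs were called (61.8%; 206 at an unadjusted p under 0.05), 114 of them at 2-fold or more, with 26 up and 88 down. For 128 the arrays of the 2 ages did not overlap, which chance gives for 1.59% of miRNAs. The direction of the excess depended on the scaling: 30.7% of the calls were rises, but 61.6% with the 75th percentile over all names, 51.3% with median scaling, 57.2% with quantile normalization, 60.2% in the deposited table and 71.4% with no scaling. In the same order, the median change of all tested miRNAs moved from -0.35 to 0.30, 0.01, 0.21, 0.31 and 0.64. With normexp background correction it was 16.2% with a median of -1.18, and miR-29c*, miR-29a*, miR-155, miR-34b-3p, miR-34c*, miR-10b and miR-222 changed sign. With camera and an estimated correlation 0 of 17 lists were called (4 at an unadjusted p under 0.05, 0 on ranks). With the preset correlation 7 were: let-7, Dlk1-Dio3, the miR-322 cluster, the miRNAs hosted by H19, Igf2 and Mest, miR-29, miR-30 and the leukocyte list. Without day 14 replicate 5 the Dlk1-Dio3 list was called (adjusted p = 0.00848). With brightness as a covariate, the calls of let-7e (-0.05), miR-15b (-0.13), miR-126-5p (0.21), miR-200a (0.05), miR-92a (0.06), miR-467b (-0.07), miR-466a-3p (-0.315), miR-669c (-0.27) and mghv-miR-M1-2 (-0.01) were lost as well. Calls were gained in that fit by let-7a (0.745), miR-30c (0.90), miR-30d (0.695), miR-106b (-0.89), miR-200b (0.53), miR-221 (0.57), miR-486 (0.90) and miR-669b (-1.45). There, miR-200c turned to a called rise (0.54) and miR-144 to a called fall (-2.60). Of the 64 named changes called in both fits, 13 were smaller by more than 0.5 on the log2 scale, such as miR-34b-5p (0.71), miR-214 (-1.07) and miR-127 (-3.42), and 15 were larger, such as miR-208b (-3.71), miR-376a (-5.60) and miR-150 (2.54).

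**Figure D3:**
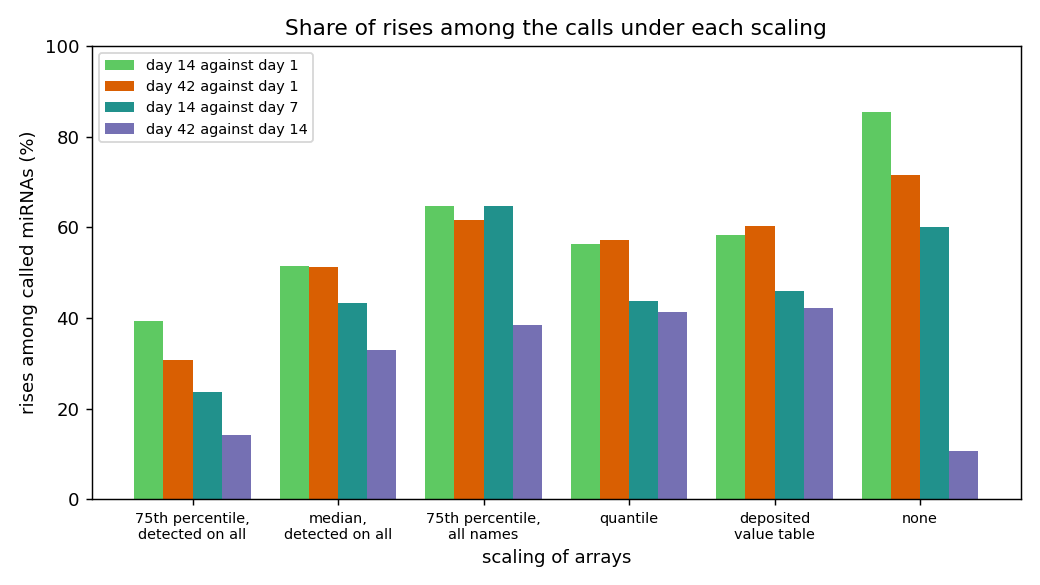
Share of rises among the called miRNAs (percent) under each scaling of the arrays, for 4 comparisons of ages. For day 42 against day 1 the share goes from 30.7% with the main scaling to 71.4% with none.

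Day 14 against day 1 covers the time in which most alveoli form. The miR-29 family had already risen, miR-29b by 2.77 ± 0.62 on the log2 scale (adjusted p = 0.000754), miR-29c by 2.42 ± 0.32 (adjusted p = 1.26e-06) and miR-29a by 1.99 ± 0.23 (adjusted p = 1.43e-07). Again 41 of 42 Dlk1-Dio3 members fell (median -2.05, negative under every scaling), and so did all 4 tested miRNAs of H19, Igf2 and Mest (median -1.77, negative under every scaling, and -0.97 over the 3 detected on all arrays of both ages). Other large rises were those of miR-153 with 2.52 ± 0.66, from a level detected on 2 of 5 day 1 arrays, miR-101a with 2.15 ± 0.49 and the blood cell miRNA miR-142-5p with 2.02 ± 0.47. The largest falls were those of miR-409-3p with -3.25 ± 0.27 (detected on 1 of 5 day 14 arrays), miR-411* with -3.06 ± 0.23, miR-541 with -3.01 ± 0.25 (detected on 3 of 5), miR-431 with -3.001 ± 0.21, miR-433 with -2.88 ± 0.25 (detected on 1 of 5). Beside these stood miR-675-3p of H19, which fell at least 7.21-fold and was detected on 0 of 5 day 14 arrays.

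Of the lists at day 14, let-7 had 6 of 9 members higher and called, among them let-7c with 0.75 and let-7b with 0.72, and the miR-30 family 3 of 5, among them miR-30a with 0.94. In the family of miR-15, miR-16 and miR-195 3 of 5 rose and 1 fell, with miR-195 rising by 1.25 and miR-497 by 1.09. The leukocyte list had 5 of 8 rises and the endothelial list 3 of 4, with miR-146b rising by 1.03, miR-146a by 0.92 and miR-126-3p by 0.80. The medians of these 5 lists were positive under every scaling. The adjusted p with an estimated correlation was 0.089 for Dlk1-Dio3, 0.22 for H19, Igf2 and Mest, 0.263 for miR-29, miR-30 and leukocytes, 0.4 for let-7 and 0.306 for the endothelial and the miR-15, miR-16 and miR-195 lists. For the miR-17 clusters, 5 of 10 members fell (median -0.38, adjusted p = 0.713 with an estimated correlation, but 0.01 with the 75th percentile over all names and 0.72 with no scaling). In the miR-322 cluster it was 4 of 10 (3 when adjusted over the list alone; median -0.23, adjusted p = 0.777 with an estimated correlation, but positive with the 75th percentile over all names, quantile normalization, no scaling and the deposited table). Of the remaining lists, 2 of 11 epithelial miRNAs rose and 1 fell, 2 of 6 multiciliated cell miRNAs rose, 1 of 7 mesenchymal miRNAs rose and 3 fell, and 1 of 3 red blood cell miRNAs rose (adjusted p = 0.713, 0.713, 0.813 and 0.361 with an estimated correlation). In the Sfmbt2 cluster 1 of 15 rose (adjusted p = 0.713 with an estimated correlation), of the 2 markers of other organs miR-219 rose by 1.57 (adjusted p = 0.0339), and of 4 striated muscle miRNAs limma called 0 (0 at an unadjusted p under 0.05 as well; adjusted p = 0.777 with an estimated correlation). Of the 3 virus names, the check of unspecific signal, 2 were called: mghv-miR-M1-2 fell by 1.08 and mcmv-miR-M23-1-5p by 0.48 (list median -0.48, but 0.61 with no scaling; adjusted p = 0.777 with an estimated correlation). As at day 42, such falls may come from the division by the array factor, which averaged 3239 at day 14 and 1539 at day 1.

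Here 173 of 322 miRNAs were called (68 up and 105 down; 192 at an unadjusted p under 0.05), 90 at 2-fold or more, and 114 showed no overlap (chance 0.794%). With camera 0 of 17 lists were called with an estimated correlation (2 at an unadjusted p under 0.05, 0 on ranks). With the preset one 7 were: let-7, Dlk1-Dio3, H19, Igf2 and Mest, miR-29, miR-30, the miR-15, miR-16 and miR-195 family and leukocytes. Without day 14 replicate 5 the Dlk1-Dio3 list was called (median -2.27, adjusted p = 0.00625). The share of rises was 39.3% but 64.6% with the 75th percentile over all names, 51.5% with median scaling, 56.4% with quantile normalization, 58.3% in the deposited table and 85.5% with no scaling. With normexp the number of calls was 52 (65.4% rises) and miR-153 changed sign. Without the dim arrays, which include day 1 replicates 4 and 5, the rises were smaller: 1.71 for miR-29b, 1.61 for miR-153, 1.84 for miR-29c, 1.20 for miR-101a and 1.26 for miR-142-5p, each still past the threshold. With brightness as a covariate miR-29c still rose (1.48, adjusted p = 0.00031), but the calls of miR-29b (0.57, adjusted p = 0.305), miR-153 (0.21, adjusted p = 0.784), miR-101a (0.47, adjusted p = 0.319) and miR-142-5p (0.41, adjusted p = 0.355) were lost.

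Day 4 against day 1 and day 7 against day 4 ask what changes in the first week, and few miRNAs were called. From day 1 to day 4 the cluster partners miR-195 and miR-497 rose by 0.71 ± 0.13 and 0.68 ± 0.12 on the log2 scale (adjusted p = 0.00196 for both). In the same step miR-675-3p of H19 fell by 0.91 ± 0.14 (adjusted p = 0.00068; detected on 4 of 5 day 4 arrays), miR-301b fell by 0.75 ± 0.19 (adjusted p = 0.0436) and the hypoxia-induced miR-210 fell by 0.54 ± 0.13 (adjusted p = 0.024). From day 4 to day 7 the 1 called miRNA was again miR-675-3p, which fell by 0.77 ± 0.14 (adjusted p = 0.00694). All 42 Dlk1-Dio3 members had lower means at day 4 than at day 1 (median -0.50, negative under every scaling), but 0 were called by limma over all miRNAs (21 at an unadjusted p under 0.05) and 2 when adjusted over the list alone. Among the miRNAs of H19, Igf2 and Mest 1 of 4 fell over all miRNAs and 2 when adjusted over the list alone.

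From day 1 to day 4, 5 of 322 miRNAs were called (2 up and 3 down; 52 at an unadjusted p under 0.05), 0 at 2-fold or more, and 14 showed no overlap (chance 0.794%). The 5 called were among these 14. From day 4 to day 7 it was 1 (15 at an unadjusted p under 0.05; 3 without overlap). The count of day 4 against day 1 was 12 without day 14 replicate 5, 8 without day 4 replicate 1, and 3 without day 1 replicates 1, 2 or 5 or day 4 replicates 2, 4 or 5, and it was 0 with only the 2 ages in the fit. It was higher with a floor 4 times as high (14), with brightness as a covariate (28) and with array weights (43, from a fit that did not converge). When single arrays were left out, the calls of miR-195, miR-497 and miR-675-3p held. With no scaling 3 others were called and none of the 5, with miR-195 at 1.07 (adjusted p = 0.084), miR-497 at 1.04 (adjusted p = 0.107) and miR-675-3p at -0.54 (adjusted p = 0.179). With normexp miR-195 and miR-497 were the 2 calls. That of miR-301b was lost in 17 of 24, that is in all but those of day 1 replicate 4, day 7 replicate 3, day 14 replicates 2 to 5 and day 42 replicate 4 (-0.80 to -0.65, adjusted p up to 0.129). That of miR-210 was lost in 6 of 24, namely without day 1 replicates 1, 2 or 5 or day 4 replicates 2, 4 or 5 (-0.55 to -0.47, adjusted p from 0.0512 to 0.108). The share of rises among so few calls went from 40% to 57.1% with the 75th percentile over all names, 62.5% with quantile normalization, 83.3% in the deposited table and 100% with no scaling or normexp. The single call of day 7 against day 4 was lost with quantile normalization, no scaling, normexp and the deposited table.

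Day 14 against day 7 separates the end of the first week from the time when the alveolar walls thin, and here more miRNAs were called than in either earlier step. This step is longer than each of those, and day 7 was not compared with day 1. Dim arrays also lay at day 1 and day 4, but not at day 7 or day 14. The counts therefore do not place the onset of the changes. By day 14 miR-29c rose by 1.83 ± 0.32 on the log2 scale (adjusted p = 9.57e-05), miR-29a by 1.79 ± 0.23 (adjusted p = 2.2e-06) and miR-29c* by 1.09 ± 0.18. Also higher were miR-146b, a brake on inflammatory signalling, with 1.09 ± 0.13, miR-22* with 0.99 ± 0.16 and the red blood cell miRNA miR-486 with 0.98 ± 0.26. Over the same week 40 of 42 Dlk1-Dio3 members fell (41 when adjusted over the list alone; median -1.41, negative under every scaling and 0.01 with normexp). Its largest falls were miR-380-3p with -2.28 ± 0.30 (detected on 2 of 5 day 14 arrays), miR-541 with -2.14 ± 0.25 (3 of 5), miR-409-3p with -2.13 ± 0.27 (1 of 5), miR-411* with -2.10 ± 0.23, miR-154* with -2.07 ± 0.24 (2 of 5) and miR-431 with -2.07 ± 0.21.

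From day 7 to day 14 also 5 of 10 members of the miR-17 clusters fell, among them miR-18a by 1.15 and miR-17 by 0.60 (median -0.44, negative under every scaling). So did 4 of 10 of the miR-322 cluster, among them miR-351 by 1.62 and miR-503 by 1.27 (median -0.28, but 0.08 with the 75th percentile over all names, 0.01 with quantile normalization, 0.09 with no scaling and 0.03 in the deposited table), and 3 of 4 of the miRNAs of H19, Igf2 and Mest. In the leukocyte list 3 of 8 rose (4 when adjusted over the list alone; median positive under every scaling). In all, 101 of 322 miRNAs were called (24 up and 77 down; 124 at an unadjusted p under 0.05), 54 at 2-fold or more, and 119 showed no overlap (chance 0.794%). The count was 156 with the 75th percentile over all names, 174 without the dim arrays and 9 with normexp. There miR-380-3p, miR-541, miR-409-3p and miR-154* were at 0.08, 0.01, 0.12 and 0.01. The share of rises was 23.8% but 64.7% with the 75th percentile over all names, 43.3% with median scaling, 43.6% with quantile normalization, 45.9% in the deposited table, 60% with no scaling and 66.7% with normexp.

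Day 42 against day 14 compares the mature lung with the lung at the end of the main wave of alveolar formation. The miR-29 rise went on, with miR-29a gaining 1.83 ± 0.24 (adjusted p = 4.21e-06), miR-29c 1.58 ± 0.34 (adjusted p = 0.000946) and miR-29c* 1.095 ± 0.19. The immune cell miRNAs miR-155 and miR-150 rose by 1.16 ± 0.22 (adjusted p = 0.000198) and 1.04 ± 0.33 (adjusted p = 0.0166), and miR-34c* of multiciliated cells rose by 1.08 ± 0.26. The miR-322 cluster fell in all 10 tested members (median -1.001, negative under every scaling, adjusted p = 0.127 with an estimated correlation), miR-322 by 0.98 and miR-542-5p by 1.03. Of the Dlk1-Dio3 members 32 of 42 fell (median -1.41, negative under every scaling, adjusted p = 0.127 with an estimated correlation). The largest falls were those of miR-376a (-2.50 ± 0.56, detected on 3 of 4 day 42 arrays), miR-136 (-2.45 ± 0.64, 3 of 4), miR-379 (-2.25 ± 0.24), miR-136* (-2.25 ± 0.35, 1 of 4) and miR-411 (-2.17 ± 0.25, 3 of 4). Outside these clusters miR-551b fell by 2.68 ± 0.64 (adjusted p = 0.00207).

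Also in this step, 4 of 8 leukocyte miRNAs rose (median 0.40, positive under every scaling, adjusted p = 0.103 with an estimated correlation), 2 of 3 in the miR-29 family (adjusted p = 0.127 with an estimated correlation) and 2 of 6 in the multiciliated cell list (median 0.60, -0.05 with normexp, adjusted p = 0.187 with an estimated correlation). Among the let-7, miR-30, endothelial and red blood cell lists limma called 0 members (0 at an unadjusted p under 0.05 as well). In the miR-17 clusters 4 of 10 fell, and in the Sfmbt2 cluster 6 of 15 (median -0.47, but 0.04 in the deposited table; adjusted p = 0.692 with an estimated correlation for both lists). Altogether 105 of 322 miRNAs were called (15 up and 90 down; 124 at an unadjusted p under 0.05), 53 at 2-fold or more, and 96 showed no overlap (chance 1.59%). With camera 0 of 17 lists were called with an estimated correlation (4 at an unadjusted p under 0.05, 0 on ranks). With the preset one 5 were: Dlk1-Dio3, the miR-322 cluster, miR-29, multiciliated cells and leukocytes. The call of miR-150 was lost without day 42 replicate 4 (0.81, adjusted p = 0.0716) or day 14 replicate 5 (0.90, adjusted p = 0.0532). The fall of miR-551b was -1.92 without day 14 replicate 5, and that of miR-136 was -1.81 without day 42 replicate 4. The share of rises was 14.3% but 38.4% with the 75th percentile over all names, 33.0% with median scaling, 41.2% with quantile normalization and 42.3% in the deposited table, and 10.8% with no scaling and 13.6% with normexp. The count of calls was 65 with no scaling and 22 with normexp, where miR-155 and miR-34c* were at -0.02 and -0.03.

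A last contrast asked for miRNAs whose mean over days 4, 7 and 14 lies above or below both ends of the series. Of the named peaks, the largest was that of miR-551b, with 2.57 ± 0.40 on the log2 scale (adjusted p = 5.04e-05). Its mean was 9.18 at day 1, 10.4 at day 4, 11.1 at day 7, 7.96 at day 14 and 5.28 at day 42. The day 14 mean thus lay below that of day 1, and it held replicate 5 at 11.01 against 7.20 on the other day 14 arrays. Other named peaks were miR-218, which comes from the Slit genes, with 1.44 ± 0.19 (adjusted p = 1.22e-05), miR-455* with 1.12 ± 0.23 and miR-340-5p with 0.93 ± 0.29. From the miR-322 cluster came miR-542-3p with 0.94 ± 0.22 and miR-450a-5p with 0.91 ± 0.20. Dips were smaller: miR-223 of myeloid cells was lower at days 4 to 14 by -0.70 ± 0.11 (adjusted p = 3.22e-05). It was followed by miR-34c* (-0.66 ± 0.16) and miR-34b-3p (-0.66 ± 0.20) of multiciliated cells, miR-805 (-0.58 ± 0.19), miR-483 of Igf2 (-0.51 ± 0.17) and miR-139-5p (-0.50 ± 0.16). In all 54 of 322 miRNAs were called (44 peaks and 10 dips; 148 at an unadjusted p under 0.05, before the demand on the means), 4 at 2-fold or more, and 16 with normexp. The call of miR-340-5p was lost without day 42 replicate 4 (0.73, adjusted p = 0.0508) and that of miR-483 without day 42 replicate 1 (-0.44, adjusted p = 0.054).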

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

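The tests of array brightness, of the scaling and the floor, and of the place of day 14 replicate 5 between the ages were chosen only after the result was seen, whereas the test of the slide was fixed beforehand. Of 314 groups of arrays, each 1 named miRNA or array measure at 1 age, 36 held an array whose gap to the nearest other exceeded Dixon's 95% limit (11.5%), where chance gives about 1 in 20. In 5 of the 36 all other arrays lay at the floor, where any value above it counts as apart, so that the share cannot be held against chance as it stands. The gap is given below as a share of the group's range. Day 42 replicate 4 accounted for 14 of the 36 and day 14 replicate 5 for 13.

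Arrays of the same age differed along 1 main axis: the first component of the deviations from the age means held 57.3% of their variance. Beside age, 215 miRNAs had a slope on array brightness, against at most 192 in the other 99 reorderings within ages, such as 3.09 per doubling for miR-144, 2.02 for miR-29b and -1.12 for miR-214, while the slide had an effect on 0 miRNAs in limma, so that the slide as the source is argued against. Brightness therefore may account for the axis, although so high a number in the reorderings shows how much of the structure a few arrays carry. The dim arrays were day 1 replicates 4 and 5, day 4 replicates 1 and 3 and day 42 replicate 4, at 52.8% to 71.5% of the median of their age, and brightness itself was 1.01 higher on the log2 scale at day 42 than at day 1 (exact permutation test, two-sided p = 0.0397). What made arrays dim, such as the amount or the state of the RNA, was not recorded, and no biological explanation was tested, since the design gives no group within an age.

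Day 42 replicate 4, a dim array, stood apart for miR-29b (0.877; level 10.40 against a mean of 12.41 on the other day 42 arrays), miR-29c (0.846; 12.08 against 12.70), miR-146b (0.93; 9.71 against 9.48), miR-369-5p (1; 3.04 against the floor of 2.86), miR-551b (0.893; 4.01 against 5.70), miR-218 (0.876; 8.73 against 9.55), miR-455* (0.832; 4.74 against 5.46), miR-340-5p (0.943; 5.94 against 7.27), miR-200c (0.925; 12.14 against 11.25), miR-182 (0.956; 6.34 against 5.68), miR-34b-5p (0.975; 10.40 against 11.92), miR-221 (0.836; 10.53 against 9.71), miR-144 (0.935; 7.27 against 10.91) and miR-219 (0.956; 5.10 against 6.93).

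Day 14 replicate 5 stood apart for miR-29c (0.924; 9.78 against 11.26), miR-29a (0.884; 11.08 against 12.57), miR-29c* (0.838; 5.50 against 6.40), miR-101a (0.751; 10.02 against 10.87), miR-450a-5p (0.786; 9.92 against 10.16) and miR-551b (0.922; 11.01 against 7.20), and for the Dlk1-Dio3 members miR-409-3p (0.822; 4.48 against 2.99), miR-541 (0.806; 5.22 against 3.61), miR-431 (0.781; 5.98 against 4.52), miR-433 (1; 3.53 against the floor), miR-380-3p (0.934; 4.68 against 2.89), miR-154* (0.769; 5.24 against 3.64) and miR-411 (0.72; 7.20 against 6.11). Each of these levels lay on the side of the day 7 mean. Each day 7 and day 14 array was placed on a scale from day 7 at 0 to day 14 at 1, over the miRNAs called at 2-fold or more between the other arrays of these ages, a set that differed by array (68 miRNAs for this one, 53 to 60 for the others). This array lay at 0.365, above the day 7 arrays (-0.107 to 0.092) and below the other day 14 arrays (1.056 to 1.286, on a scale whose day 14 mean held this array), which argues against a day 7 sample under a day 14 label. Its brightness was 95.76% of the median of its age, which argues against a dim array. A lung that developed more slowly, or a sample taken at an age between the 2, may be candidate explanations, but neither was tested, since the labels give no weight or litter.

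The fall of the Dlk1-Dio3 miRNAs from day 1 to day 42 and the larger number of falls than rises in that comparison were weighed together. With no scaling the median of the list was still -2.59, and over its 21 members above the list's median level it was -3.94, values that argue against the scaling and against the floor as the source of the fall. For all miRNAs it was otherwise: rises made up 71.4% of the calls with no scaling, so that the excess of falls may come from the scaling. As a hypothesis, the fall of this imprinted region with age is biological, and which cells lose these miRNAs is open.

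Other arrays stood apart in single values. On day 42 replicate 1, miR-431 (1; 3.14 against the floor), miR-411* (1; 3.27 against the floor) and miR-411 (0.848; 5.13 against 3.84) were higher, and on day 42 replicate 2 miR-29c* (0.865; 7.24 against 7.34) was lower than on the other day 42 arrays. On day 14 replicate 1, miR-675-3p was the 1 value above the floor (1; 3.20). On day 1 replicate 3, miR-483 was lower (0.743; 5.18 against 6.20), and so were miR-335-5p (0.711; 10.94 against 11.93) and mcmv-miR-m88-1 (0.83; 5.76 against 6.86) on day 1 replicate 4. Day 4 replicate 1, a dim array, had 282 detected miRNAs against a mean of 325 on the other day 4 arrays (0.735).

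In data outside the miRNA signals, the control probe dmr_285 differed between the ages by -1.08 on the log2 scale (10.97 at day 42, 12.05 at day 1; exact permutation test, two-sided p = 0.00794, lower on 4 of 4 arrays), and the control probes of the hur series by 0.29 in the other direction (exact permutation test, two-sided p = 0.00794). Of the virus names, 2 were detected on every array (mcmv-miR-M23-1-5p and mcmv-miR-m88-1), mghv-miR-M1-2 on 23 of 24, mcmv-miR-M87-1 on 5, mcmv-miR-M23-1-3p on 4, mghv-miR-M1-8 on 2 and mcmv-miR-m01-2 on 1.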

How the results depend on the processing

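The fit without the 5 dim arrays and the fit with array brightness as a covariate were chosen only after the result was seen, whereas the other alternatives were fixed beforehand. The scan date was not run as a block, since all arrays were scanned on 1 day, and the values with array weights come from a fit that did not converge. Signal over background limits the low end, where a miRNA not detected at an age has a bound and no fold. Replicate numbers do not pair the arrays: the mean correlation of deviations from the age means was -0.0272 over 46 pairs with the same number (-0.857 to 0.839, 18 of them over 0.1) and 0.0142 over pairs with different numbers, and 2 of 24 arrays correlated best with 1 of their own number. The cause of the differences below was not tested except where it is given.

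Over the 5 ages the count was 211 and kept within 1.5 times of that under 18 alternatives (147 to 262), the exception being normexp with 92. For day 42 against day 1 it was 199, with 142 to 241 under 20 alternatives, and 114 at 2-fold or more. For day 14 against day 1 it was 173, with 121 to 248 under 19, 52 with normexp and 90 at 2-fold or more. For day 14 against day 7 it was 101, with 83 to 120 under 13 alternatives; it was 156 with the 75th percentile over all names, 9 with normexp, 58 when detected on all arrays (fewer miRNAs tested), 210 with array weights, 168 with only the 2 ages, 174 without the dim arrays, 153 with brightness as a covariate and 54 at 2-fold or more. For day 42 against day 14 it was 105, with 73 to 137 under 16; it was 65 with no scaling, 22 with normexp, 63 when detected on all arrays, 168 with array weights and 53 at 2-fold or more. The transient count of 54 lay between 37 and 79 under 19 and was 16 with normexp. Normexp adds its offset of 50 before each array is divided by its factor, so that dim arrays get a higher floor, which its construction shows. It also used the median spot signal and the median local background, so its counts cannot be put down to the offset alone.

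Day 4 against day 1 gave 5, with 4 to 7 under 10 alternatives; it was 8 with quantile normalization, 3 with no scaling, 2 with normexp, 14 with a floor 4 times as high, 3 with a floor 4 times as low, 3 when detected on all arrays, 9 when detected on at least 1, 43 with array weights, 0 with only the 2 ages in limma (fewer arrays, and 52 at an unadjusted p under 0.05 with all ages), 28 with brightness as a covariate and 0 at 2-fold or more. Day 7 against day 4 gave 1; it was 0 in limma with quantile normalization, no scaling, normexp, a floor 4 times as high or as low, detection on all arrays, the deposited table or without the dim arrays, and at 2-fold or more (15 at an unadjusted p under 0.05 with the settings of the report), and 7 with array weights. With the slide as a block the counts over the 5 ages, for day 42, day 14 and day 4 against day 1, day 7 against day 4, day 14 against day 7 and day 42 against day 14, and for the transient contrast were 215, 197, 172, 5, 1, 104, 103 and 55. With the replicate number they were 205, 193, 171, 4, 1, 100, 94 and 49. Without the dim arrays the count was 236 over the 5 ages, 196 for day 14 against day 1, 6 for day 4 against day 1, 132 for day 42 against day 14 and 46 for the transient contrast. With brightness as a covariate these were 224, 170, 28, 137 and 61, and the count for day 42 against day 1 was 204.

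Among lists, camera with an estimated correlation called 0 in the 3 comparisons. For day 14 against day 1 it called 1 (Dlk1-Dio3) with the 75th percentile over all names, median scaling, quantile normalization, no scaling, a floor 4 times as high, detection on at least 1 array or the deposited table, 2 with no filter, and 7 with the preset correlation. For day 42 against day 14 it called 2 (Dlk1-Dio3 and the miR-322 cluster) with the 75th percentile over all names, median scaling and quantile normalization, 2 with normexp (miR-29 and leukocytes), 2 with no filter (the miR-322 cluster and leukocytes), 1 with the deposited table and 5 with the preset correlation. For day 42 against day 1 it called 1 (Dlk1-Dio3) with the 75th percentile over all names, median scaling, quantile normalization, a floor 4 times as high, only the 2 ages or the deposited table, 1 with normexp (miR-29), 3 with no filter (Dlk1-Dio3, the miRNAs of H19, Igf2 and Mest, and leukocytes) and 7 with the preset correlation.

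Leaving out each array in turn gave 193 to 224 over the 5 ages, 183 to 208 for day 42 against day 1, 155 to 190 for day 14 against day 1, 3 to 12 for day 4 against day 1, 1 to 1 for day 7 against day 4, 89 to 112 for day 14 against day 7, 88 to 106 for day 42 against day 14 and 38 (without day 1 replicate 4) to 71 (without day 1 replicate 2) for the transient count. Lists numbered 0 to 1 for day 14 and for day 42 against day 1 (1 without day 14 replicate 5) and 0 to 0 for day 42 against day 14. The difference in detected miRNAs per array, -6.9, ran from -16.5 without day 1 replicate 4 to 0.6 without day 42 replicate 4, and was -9.3 for signals well above background (exact p = 0.619) and -13.67 without the dim arrays (exact p = 0.4). For single miRNAs and lists, 64 values lost their call, 25 gained it and 38 changed sign without being called either way, while 4793 did none of these. The ranges of those with a change of sign were -0.38 to 0.036 for miR-106b, -0.012 to 0.24 for miR-200b, -0.32 to 0.068 for miR-200c, -0.02 to 0.16 for miR-143, -0.088 to 0.21 for miR-221, -0.12 to 1.48 for miR-144, -0.009 to 1.60 for miR-133b and -0.15 to 1.44 for miR-133a, all for day 42 against day 1. For list medians they were -0.28 to 0.09 for mesenchyme and -0.077 to 1.52 for striated muscle in that comparison, and for day 14 against day 1 -0.073 to 0.24 for multiciliated cells, -0.12 to 0.015 for mesenchyme and -0.005 to 0.18 for the Sfmbt2 cluster. For day 42 against day 14 they were -0.067 to 0.091 for let-7, -0.13 to 0.085 for miR-30, -0.18 to 0.012 for the miR-15 family, -0.17 to 0.085 for epithelium, -0.14 to 0.038 for endothelium and -0.56 to 0.15 for striated muscle.

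Over all alternatives and leave-outs, values of named miRNAs kept direction and side of the threshold in 6265 cases, stood at 0 in 4, lost the call in 218, gained it in 107 and changed sign in 128, of which 62 were called in the report or under the alternative. Values of lists kept both in 2163 cases, stood at 0 in 6, gained a call in 51 and changed sign in 120, none of them called by camera either way. The changes of sign for named miRNAs follow, for day 42 against day 1 unless another comparison is given. With the 75th percentile over all names they were let-7e 0.087, miR-106b 0.44, miR-494 0.19, miR-483 0.30, miR-15b 0.073, miR-200c 0.50, miR-342-3p 0.12, miR-128 0.45, miR-669f 0.41, miR-467b 0.26, miR-669a 0.28, miR-466a-3p 0.26 and mcmv-miR-M23-1-5p 0.44. With median scaling they were miR-106b 0.15, miR-483 0.002, miR-200c 0.21, miR-128 0.16, miR-669f 0.12 and mcmv-miR-M23-1-5p 0.15. With quantile normalization they were miR-483 0.68, miR-30d -0.021, miR-16 -0.25, miR-200b -0.013, miR-182 0.22, miR-143 -0.15, miR-451 -0.12, miR-128 0.57, miR-669f 0.52, miR-467b 0.61, miR-669a 0.69, miR-466a-3p 0.66, miR-669c 0.26, miR-669b 0.41 and mcmv-miR-M23-1-5p 0.28. With no scaling they were let-7e 0.43, miR-19b 0.25, miR-106b 0.79, miR-92a 0.22, miR-20a 0.12, miR-494 0.53, miR-450a-5p 0.20, miR-483 0.64, miR-15b 0.42, miR-200c 0.84, miR-182 0.24, miR-199a-3p 0.23, miR-342-3p 0.47, miR-128 0.79, miR-669f 0.76, miR-467b 0.60, miR-669a 0.62, miR-466a-3p 0.60, miR-669c 0.29, miR-669b 0.17 and mcmv-miR-M23-1-5p 0.79. In the deposited table they were miR-483 0.80, miR-16 -0.088, miR-182 0.40, miR-449c 0.11, miR-143 -0.072, miR-128 0.56, miR-669f 0.46, miR-467b 0.69, miR-669a 0.84, miR-466a-3p 0.74, miR-669c 0.35, mcmv-miR-M23-1-5p 0.12 and mghv-miR-M1-2 0.046. With normexp they were miR-29c* -0.32, miR-29a* -1.34, miR-155 -0.50, miR-34b-3p -0.59, miR-34c* -0.55, miR-10b -0.16, miR-221 -0.15, miR-222 -0.19, miR-486 -0.18, miR-1 -0.036, miR-133b -0.22, miR-133a -0.54, miR-219 -0.80 and mcmv-miR-m88-1 -0.84; for day 14 against day 1 miR-153 -0.12; for day 14 against day 7 miR-380-3p 0.082, miR-541 0.006, miR-409-3p 0.12 and miR-154* 0.009; for day 42 against day 14 miR-155 -0.019 and miR-34c* -0.034. With array weights they were miR-16 -0.15, miR-200b -0.003, miR-429 -0.028, miR-143 -0.17, miR-221 -0.062, miR-1 -0.043, miR-133b -0.32 and miR-133a -0.46. With the slide as a block it was miR-143 -0.02. Without the dim arrays they were miR-200c 0.11, miR-1 -0.21, miR-133b -0.36 and miR-133a -0.50. With brightness as a covariate they were miR-92a 0.064, miR-494 0.34, miR-483 0.28, miR-30e -0.42, miR-15a -0.26, miR-200c 0.54, miR-429 -0.073, miR-143 -0.23, miR-342-3p 0.30, miR-451 -0.084, miR-144 -2.60, miR-1 -1.58, miR-133b -0.71, miR-133a -0.85, miR-219 -0.79 and mcmv-miR-M23-1-5p 0.17.

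The changes of sign of list medians follow in the same way. With the 75th percentile over all names they were the Sfmbt2 cluster 0.26 and the virus names 0.44; for day 14 against day 1 the miR-17 clusters 0.006, the miR-322 cluster 0.15 and mesenchyme 0.34; for day 42 against day 14 let-7 0.26, miR-30 0.26, the miR-15 family 0.18, epithelium 0.19, mesenchyme 0.11, endothelium 0.21 and striated muscle 0.009. With median scaling they were the virus names 0.15; for day 14 against day 1 mesenchyme 0.089; for day 42 against day 14 let-7 0.22, miR-30 0.21, the miR-15 family 0.14, epithelium 0.15, mesenchyme 0.068 and endothelium 0.16. With quantile normalization they were mesenchyme -0.15, the Sfmbt2 cluster 0.66 and the virus names 0.28; for day 14 against day 1 the miR-322 cluster 0.17 and mesenchyme 0.15; for day 42 against day 14 mesenchyme 0.13 and endothelium 0.13. With no scaling they were the miR-17 clusters 0.24, the Sfmbt2 cluster 0.60 and the virus names 0.79; for day 14 against day 1 the miR-17 clusters 0.72, the miR-322 cluster 0.86, mesenchyme 1.05 and the virus names 0.61. In the deposited table they were mesenchyme -0.072, the Sfmbt2 cluster 0.74 and the virus names 0.12; for day 14 against day 1 the miR-322 cluster 0.23 and mesenchyme 0.12; for day 42 against day 14 epithelium 0.018, mesenchyme 0.10, endothelium 0.051 and the Sfmbt2 cluster 0.04. With normexp they were epithelium -0.33, multiciliated cells -0.57, mesenchyme -0.37 and striated muscle -0.38; for day 14 against day 1 epithelium -0.16, multiciliated cells -0.48, striated muscle -0.24 and the Sfmbt2 cluster -0.62; for day 42 against day 14 let-7 0.036, miR-30 0.004, multiciliated cells -0.047 and the virus names -0.46. With array weights they were epithelium -0.028, mesenchyme -0.17 and striated muscle -0.39; for day 14 against day 1 mesenchyme 0.081, striated muscle -0.20 and the Sfmbt2 cluster -0.033. With the brightest probe they were mesenchyme -0.047; for day 14 against day 1 the Sfmbt2 cluster -0.034; for day 42 against day 14 let-7 0.022. Among miRNAs detected on all arrays it was for day 14 against day 1 the Sfmbt2 cluster -0.075. Among those detected on at least 1 array they were striated muscle -0.17 and the virus names 0.13; for day 14 against day 1 striated muscle -0.17 and the virus names 0.003. With no filter they were striated muscle -0.17; for day 14 against day 1 striated muscle -0.17. With the slide as a block they were mesenchyme -0.02; for day 42 against day 14 miR-30 0.003. Without the dim arrays they were striated muscle -0.43; for day 14 against day 1 mesenchyme 0.033, striated muscle -0.76 and the Sfmbt2 cluster -0.094; for day 42 against day 14 let-7 0.11, miR-30 0.11, the miR-15 family 0.092, epithelium 0.26, endothelium 0.036, red blood cells 0.026 and striated muscle 0.33. With brightness as a covariate they were epithelium -0.073, mesenchyme -0.23, red blood cells -0.084, striated muscle -1.21 and the virus names 0.096; for day 14 against day 1 multiciliated cells -0.007, mesenchyme 0.22 and striated muscle -1.10.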

Other observations

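Of the tests in this part, those of the spread of muscle miRNAs within ages and of the leukocyte rise were chosen only after the result was seen, whereas those of the hairpin arms, of day 1 replicate 2 and of the splits were fixed beforehand. A miRNA hairpin gives 2 arms, made from the same transcript, and for 66 hairpin names both arms were tested. Arms were paired by name, and a name can stand for more than 1 hairpin. In 56 of them the arms had the same sign from day 1 to day 42. Examples are miR-22 with 1.39 and miR-22* with 1.47, both called, and the fibroblast miRNA miR-214 with -2.19 and miR-214* with -2.58. The likeness of miR-214 and miR-214* depends on the fit. Their slopes on brightness were -1.12 and 0.27 per doubling, and miR-214 was at -1.07 with brightness as a covariate. Outside the Dlk1-Dio3 region the sign was the same for 45 of 55, and the median difference between arms was 0.39 on the log2 scale, against 1.09 in random pairings of the same miRNAs, none of 10000 as small, so that a shared primary transcript may set much of the change. Wide gaps were those of miR-106b (-0.22 and -2.90 for its star arm) and miR-29b (4.02 and 1.36 for its star arm). However, miR-29b* had a mean level of 4.745, near the floor of 2.86, where a change can be cut short.

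Day 1 replicate 2 stood high for striated muscle miRNAs: miR-1 was at 14.05 on the log2 scale against 7.68 on average on the other day 1 arrays, miR-133b at 13.45, miR-133a at 12.94 and miR-208b at 10.12. Of the 3 muscle miRNAs outside the tests, 2 had their highest signal of all arrays there, miR-208a, a miRNA of heart muscle, at 7.18 (highest other array 3.39) and miR-499 at 9.19 (highest other array 4.45), while miR-206 of skeletal muscle was not detected there. Heart tissue in that dissection may be a candidate source, but it cannot be told apart here from striated muscle of the lung itself. Across the series, miR-1, miR-133a and miR-133b were detected on all 24 arrays and miR-208b on 19. Within ages the spread of the muscle mean, with the common component taken out, was 0.95 on the log2 scale and lay at percentile 100 of 10000 random lists of the same size and level, and without day 1 replicate 2 it was 0.50 and lay at percentile 99.8. Whether other samples held muscle is left open, a reading set only after this percentile was seen, since several of these miRNAs are made from shared transcripts and vary together whatever their source.

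The leukocyte mean rose by 1.28 on the log2 scale from day 1 to day 42 (exact permutation test, two-sided p = 0.00794), and the red blood cell mean differed by 0.45 (exact permutation test, two-sided p = 0.421). The difference between these 2 changes was 0.83 (exact permutation test, two-sided p = 0.19), so that more leukocytes in the tissue and more blood left in the lung cannot be told apart with 3 red blood cell miRNAs that vary between arrays. With brightness in the fit, 6 of 8 leukocyte miRNAs still rose, while the call of miR-142-3p was lost (0.03). Each array was divided by that same brightness, which was higher at day 42. Members with a negative slope on it are therefore raised in this fit, such as miR-150 (slope -0.94 per doubling, from 1.60 to 2.54). Those with a positive slope are lowered, such as miR-142-5p (slope 1.47, from 2.35 to 0.87). The fit thus does not decide whether brightness lies behind the rise of the list. The red blood cell mean holds miR-144, which went from -0.12 to 1.48 when single arrays were left out.

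Other splits of the same arrays show whether chance can be excluded, with 100 splits for each count, the real one included. Chance can be excluded, with 1 of 100 splits as large, for the count over the 5 ages (211, highest other 71), day 42 against day 1 (199, highest other 176), day 14 against day 7 (101, highest other 76) and day 42 against day 14 (105, highest other 77). Other splits of day 42 and day 1 still gave up to 176 calls, so the rank bears on the grouping and not on the size of the count. Day 14 against day 1 also ranked first (173, highest other 162), but its count was 155 without day 14 replicates 3 or 4. With so small a margin chance is not excluded for that count. The transient contrast also ranked first (54, highest other 52), but its reorderings mixed all 5 ages. They ask whether age matters at all, and not whether a level peaks or dips beside a trend. With that small margin and a count of 38 without day 1 replicate 4, chance is not excluded for the transient count. For day 7 against day 4 the real split also ranked first of 100, but with a count of 1 against 0 in limma in the others, and this call was lost under several alternatives, so that little rests on it. For day 4 against day 1 chance cannot be excluded: 9 of 100 splits gave 5 or more, and 1 gave 109, which points to a structure among these arrays. For lists, where camera called 0 with an estimated correlation, 100 of 100 splits were as large, with at most 2 for day 14 against day 1, 1 for day 42 against day 14 and 3 for day 42 against day 1.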
